A study of Rattus norvegicus with 6 samples.

How the data were processed

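The data were 6 arrays (Agilent whole rat genome, 2 colours) of ventral striatum from Buffalo rats. Per the labels, RNA of each rat was reverse transcribed, equal amounts of cDNA of 5 to 8 rats were combined into 1 pool per group, amplified RNA was made from the pool, and 0.75 µg was labelled with Cy3 or Cy5. Each of the 3 pairs of pools was hybridised on 2 arrays with the dyes exchanged, and the pool in each channel was taken from the labels. The replicate is therefore the pool, arrays are technical replicates, and no p-value over arrays concerns the groups of rats.

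Per the file headers, the images were read with Agilent Feature Extraction, with spatial detrending and the software's own dye normalization. The deposited scanner files give the mean signal and the local background median of each spot as intensity on a linear scale, not normalized, and flags for spots that are saturated, uneven or not well above background. They also give the software's log ratio, deposited as log10 of red over green, in which dim signals are replaced by the software's own values. The deposited series matrix holds the same log10 values (largest difference 0, column medians between 0 and 0.00058), so its scale and direction are those of the scanner files.

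Each array held 43628 features, of which 41372 were not controls, for 41012 probes. Intensities were background-corrected with normexp (offset 50) and normalized within arrays by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3, with no step between arrays. Spots marked as outliers were set to missing, control spots were left out, spots of a probe were averaged and saturated spots were kept. The resulting log2 ratios correlated with the software's deposited log ratio at r = 0.879 to 0.939 per array. Probes with values on all 6 arrays numbered 39494, and 38730 of them were well above background on all 4 channels of at least 1 pool. A gene with several probes was given by its brightest, which left 35720 transcripts. Names came from the array design, updated through RefSeq's gene table for GRCr8. By RefSeq accession 8031 probes were matched, by gene identifier 8676, by symbol 1392, by synonym 423 and by another listed accession 17, and 22473 kept the name of the design. Median intensity per channel ran from 318 to 1149 and was lowest in Cy5 of the tumor-bearing versus freely feeding arrays (494 and 318), which were extracted on another day. The number of arrays limits the precision.

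For each pair the direct log2 ratio was the mean of both dye orientations with signs aligned, in which a dye effect cancels. Under a rule fixed before the data were examined, a transcript passed when its direct ratio was at least 1.5-fold in size, both orientations had its sign, and the indirect ratio through the third pool, from the other 4 arrays, had its sign. Array error was taken from differences of the dye effect between pairs, which gives the SD expected for the sum of the 3 ratios around the loop. That sum divided by the square root of 3, put through the same size threshold, passed for 388 transcripts as labelled and 3 with the food-restricted versus freely feeding pair turned. Medians of 30 gene lists fixed beforehand were set against 10000 random lists of the same size matched on mean intensity over 20 bins, among transcripts with a symbol. Their percentiles describe these pools and are not tests.

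Genes named in the text were, per comparison, the 8 highest and 8 lowest past the rule with a gene symbol, up to 3 members per list past the rule with the largest ratios, and 12 genes named whatever their values. Because few transcripts passed as labelled, the rule was applied a second time with the food-restricted versus freely feeding pair turned, a choice made after seeing the data. Genes named outside it are marked as chosen after their values were seen, and some genes that the rule names are not reported here.

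The procedure was tested on simulated data of 35720 transcripts with 50 changed at each fold. For the food-restricted versus freely feeding pair it recovered 0% at 1.3-fold, 98.0% at 1.7-fold and 100.0% at 2-fold and 3-fold, with 0 unchanged transcripts called. With that pair simulated as turned, and the freely feeding pool as the changed one, it recovered 0% at every fold in both comparisons against that pool. That outcome follows from the sign conditions and tests nothing further. The simulated noise was normal with the same SD for all transcripts, so high values on single arrays were not simulated. Of 200 random lists of 25 genes in the tumor-bearing versus food-restricted comparison, 10 fell outside the central 95%, and all 20 lists shifted by 0.1 were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

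Alternatives were no background correction, normexp with offset 0, the software's log ratio, the series matrix, median centring, other filters on dim probes, thresholds of 1.3-fold and 2-fold, no sign conditions, a least-squares fit of the loop, the median over a gene's probes, kept outlier spots, each array left out, and limma over the 6 arrays with a dye term (2 residual degrees of freedom), which compares the pools. Turned pairs, a loop fit with a turned pair, subtraction of medians over 12 by 24 blocks of the array, and transcripts with a symbol alone were added after seeing the data. Where an array of a pair was left out, the ratio came from the remaining array minus the mean dye effect of the other pairs. The condition on both orientations then fell away for that pair, so its counts come from a looser rule. Groups of 2 arrays were too small for an outlier rule or for other splits of the samples.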

Results

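Gene expression was measured in the ventral striatum, the part of the basal ganglia that holds the nucleus accumbens, of Buffalo rats weighing 160 to 230 g. There were 3 groups: freely feeding rats injected with buffered saline, tumor-bearing rats that were injected under the skin with rat hepatoma cells and ate freely, and food-restricted rats brought to the body weight of the tumor-bearing group by a 33% restriction. RNA of 5 to 8 rats per group was combined into 1 cDNA pool, and each pair of pools was hybridised on 2 whole-genome rat arrays with the dyes exchanged, which gave 6 arrays. The design sets eating less in healthy rats beside bearing a small tumor. With 1 pool per group, neither response can be told apart from other differences between the pools. Median spot intensity ranged from 318 to 1149 per channel, and 93.2 to 98.9% of the features lay well above background. After filtering, 35720 transcripts were compared, 15342 of them with a gene symbol. Values are log2 ratios of the pools named, mean ± SD of the 2 dye orientations (n = 2 arrays). Because each group was 1 pool, this spread is technical, and no value tests a difference between groups of rats. The spread also holds each gene's dye effect, which cancels in the mean, so it is not the error of the mean.

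The 3 pools form a loop, so each direct ratio can be set against the ratio through the third pool. As labelled, the loop did not close. Cck, the cholecystokinin gene, was higher in the food-restricted than in the freely feeding pool (2.54 ± 0.25) and lower in the tumor-bearing than in the freely feeding pool (-2.73 ± 0.17), yet the tumor-bearing and food-restricted pools, hybridised against each other, differed by only -0.45 ± 0.06. Nrn1 (1.86 and -2.14, against -0.39) and Slc17a7 (1.48 and -1.38, against -0.26) did likewise. Across transcripts, which are not independent replicates, the direct food-restricted versus freely feeding ratio correlated with its indirect ratio at r = -0.80. The sum of the 3 ratios around the loop had an SD of 0.30 as labelled, against 0.15 expected from array error, and of 0.10 with the food-restricted versus freely feeding pair turned. The 0.10 lies below the expected SD, which also takes in any dye effect that differs between pairs and may therefore be too large. Turning both pairs that hold the tumor-bearing pool closes the loop equally well, so the arrays give the direction of the pairs only relative to each other. The array titles name the Cy5 pool first on 4 arrays and the Cy3 pool first on the 2 arrays of food-restricted versus freely feeding, but they do not say what that order means. The direction of every ratio is therefore not settled here. Values below carry the sign the labels give, and turning a pair changes that sign and not the size.

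**Figure D1:**
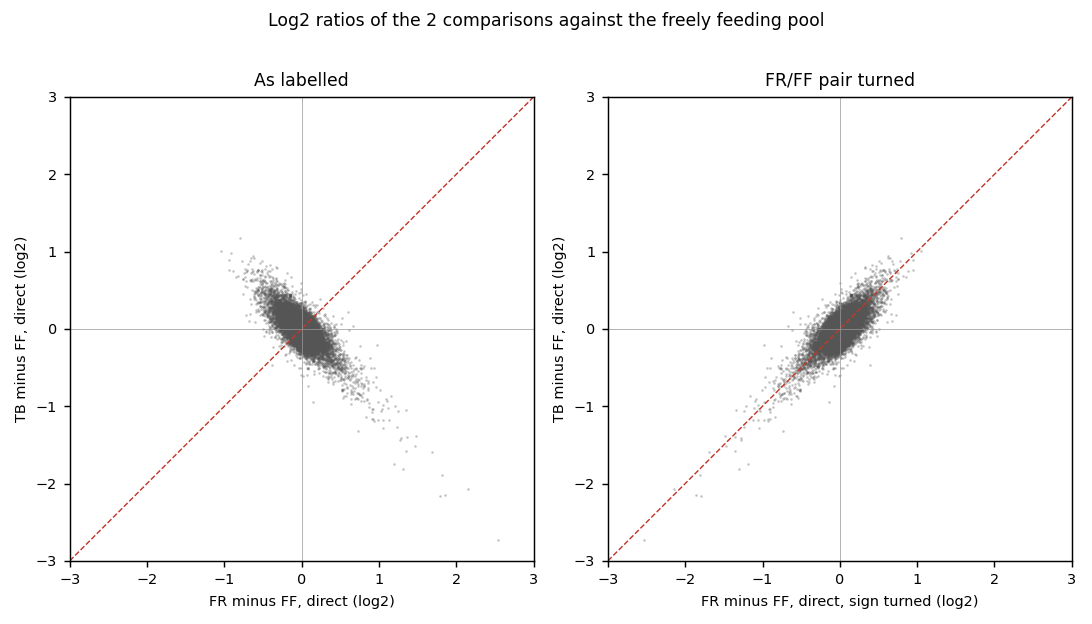
Each dot is 1 of 35720 transcripts, with the direct log2 ratio of the food-restricted (FR) over the freely feeding (FF) pool on the x axis and of the tumor-bearing (TB) over the freely feeding pool on the y axis, as labelled on the left and with the first pair's sign turned on the right, and the dashed red line marks equal values. As labelled the 2 ratios run against each other (r = -0.71 across transcripts), while the ratio of the tumor-bearing over the food-restricted pool had an SD of only 0.08.

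The food-restricted versus freely feeding pair addresses the effect of reduced food intake without a tumor. Among the 30 fixed lists the cerebral cortex list had the largest median, higher in the food-restricted pool as labelled. A second list of cortical pyramidal neuron genes moved less, with a median of 0.14 over 30 genes. Cck was 5.81-fold higher and Nrn1, which encodes neuritin, 3.62-fold (1.86 ± 0.004). Outside the cerebral cortex list, Nr4a2, an orphan nuclear receptor gene, was 3.47-fold higher (1.79 ± 0.04). Slc17a7, the vesicular glutamate transporter VGLUT1, was 2.79-fold higher (1.48 ± 0.13). Lower in the same pool was Slc5a7, the choline transporter of cholinergic neurons (-1.05 ± 0.08).

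Of the 16 measured genes in the cerebral cortex list, 14 lay above 0 and 8 had a mean at least 1.5-fold higher with both orientations above 0. The list median of 0.63 stood above all matched random lists. Among other high transcripts were Ccn3 (1.36 ± 0.27), the sulfotransferase gene Hs3st2 (1.35 ± 0.14), and the neuronal pentraxin genes Nptxr (1.35 ± 0.12), Nptx1 (1.31 ± 0.005) and Nptx2 (0.65 ± 0.08). Neuropeptide genes in the same direction were Vip (0.93 ± 0.19) and Grp (0.74 ± 0.20). The kinase gene Camk2a (0.90 ± 0.20), the GABA-B receptor subunit Gabbr2 (0.77 ± 0.09), the serotonin receptor Htr2c (0.75 ± 0.18), the collagen gene Col6a1 (0.69 ± 0.05) and Ccn2 (0.64 ± 0.11) were also higher. A second, dimmer probe gave 0.00 for Cck and 0.16 for Camk2a.

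The striatal projection neuron list lay on the other side, with a median of -0.14 over 25 genes, below all matched random lists, 5 genes above 0 and orientations at -0.06 and -0.33. None of its members reached 1.5-fold. Penk, the enkephalin precursor of indirect-pathway neurons, measured -0.47 ± 0.07 (-0.16 on a dimmer probe). Pdyn, the dynorphin precursor, measured -0.42 ± 0.12, and Tac1, the substance P precursor, -0.31 ± 0.44, which is within the spread of its orientations. The dopamine receptor genes Drd1 (-0.06 ± 0.15) and Drd2 (0.06 ± 0.15) and the peptide genes Cartpt (-0.22 ± 0.11) and Npy (0.00 ± 0.27) were closer to 0 or within the spread of the orientations. Other low transcripts were Tnnt1 (-0.94 ± 0.01), Agt, the angiotensinogen gene (-0.92 ± 0.12), Eef2-ps5, a pseudogene of an elongation factor (-0.88 ± 0.01), the striatum-enriched phosphatase gene Ptpn5 (-0.79 ± 0.14), the myelin gene Mbp (-0.78 ± 0.05, saturated in 3 of 12 channels), the calcitonin receptor Calcr (-0.76 ± 0.03) and Sncg (-0.67 ± 0.11). The dimmer probe of Calcr gave -0.03.

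Hemoglobin transcripts were higher in the food-restricted pool as labelled (Hba-a1, 0.67 ± 0.09; Hbb, 0.61 ± 0.08), and the red blood cell list had a median of 0.30 over 8 genes. Ribosomal protein genes had a median of -0.11 over 68, with 9 above 0, and the astrocyte list -0.10 over 22, with 8 above 0 and orientations at 0.01 and -0.12. The oligodendrocyte list had a median of -0.06 over 23 (1.08th percentile), with orientations at 0.02 and -0.12, and the cholinergic and GABAergic interneuron list -0.04 over 20 (2.01th percentile). The glucocorticoid-responsive list had a median of -0.04 over 25, at the 1.67th percentile, with orientations at 0.00 and -0.11, and its member Fkbp5 measured -0.32 ± 0.06 (-0.13 on a dimmer probe). Immediate-early genes had a median of 0.04 (94.2th percentile), and Fos measured -0.12 ± 0.03. Feeding neuropeptides and their receptors had a median of -0.02 (5.40th percentile). The serotonin receptor Htr2a measured 0.26 ± 0.06 and the thyroxine carrier Ttr 0.06 ± 0.03. Dimmer probes gave 0.11, 0.03 and -0.13 for Htr2a and -0.01 for Ttr. In all, 211 transcripts had a mean ratio of at least 1.5-fold with both orientations on the same side, 151 higher and 60 lower, but none also had the sign of the indirect ratio, so 0 passed the rule fixed for this comparison. With this pair's sign turned, a choice made after seeing the data, all conditions held for 211, of which 60 were higher and 151 lower. Without the array that carried the food-restricted pool in Cy3 the count as labelled was 3, with no condition on both orientations.

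The tumor-bearing versus freely feeding pair addresses the joint effect of a small tumor and the eating that goes with it. As labelled, the cerebral cortex list was lower in the tumor-bearing pool and the striatal projection neuron list higher. The second list of cortical pyramidal neuron genes moved less, with a median of -0.06 over 30 genes. Cck was 6.62-fold lower, Nrn1 4.42-fold (-2.14 ± 0.26) and Nptx1 3.52-fold (-1.82 ± 0.21), and, outside the cerebral cortex list, Nr4a2 4.46-fold (-2.16 ± 0.12). Ptpn5 was 2.25-fold higher (1.17 ± 0.35) and Slc5a7 2.00-fold (SD 0.02 on the log2 scale).

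The cerebral cortex list had a median of -0.45 over 16 genes, with 3 above 0, 7 with a mean at least 1.5-fold lower and both orientations below 0, and array medians at -0.29 and -0.69. Olfm1 (-1.75 ± 0.20), Hs3st2 (-1.58 ± 0.14), Syt17 (-1.44 ± 0.30), the cortical transcription factor gene Fezf2 (-1.41 ± 0.08), Slc17a7 (-1.38 ± 0.28) and Vip (-1.19 ± 0.22) were low. So were Htr2c (-0.85 ± 0.01), Ccn2 (-0.79 ± 0.39), Gabbr2 (-0.70 ± 0.43), Col6a1 (-0.70 ± 0.22) and Grp (-0.65 ± 0.31). The projection neuron list had a median of 0.32 over 25 genes, with 21 above 0. Its members Penk (0.68 ± 0.03, saturated in 1 of 12 channels) and Adora2a, an adenosine receptor of indirect-pathway neurons (0.62 ± 0.48), were past 1.5-fold, though second probes gave 0.14 for Penk (dimmer) and 0.32 for Adora2a (almost as bright), while Arpp21, also in the list, was lower (-0.78 ± 0.28). Pdyn measured 0.42 ± 0.01, Tac1 0.37 ± 0.16, Drd1 0.30 ± 0.10, Cartpt 0.27 ± 0.21 and Drd2 0.03 ± 0.10. Agt (0.98 ± 0.51), Ubl3 (0.94 ± 0.06), Pde2a (0.92 ± 0.38), Gnl1 (0.91 ± 0.04), Epdr1 (0.88 ± 0.12), Mbp (0.88 ± 0.02), the neurotrophin receptor Ngfr (0.76 ± 0.05), Calcr (0.64 ± 0.16) and Sncg (0.63 ± 0.33) were higher. Dimmer second probes gave -0.05 for Cck, -0.01 for Calcr and 0.44 for Mbp. The oligodendrocyte list had a median of 0.13 over 23 genes (orientations 0.22 and 0.01), ribosomal protein genes 0.12 over 68 (0.17 and 0.04) and the meninges and fibroblast list -0.12 over 17. Feeding neuropeptides and their receptors had a median of 0.06 over 38 (99.0th percentile), which was -0.02 without array 1 of the pair.

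The immediate-early list had a median of -0.11 over 35 genes (0.01th percentile), with 13 above 0. Its member Btg2 (-0.74 ± 0.05) and Dusp6 (-0.63 ± 0.002), a phosphatase gene of the ERK pathway, passed every condition as labelled and were lower in the tumor-bearing pool. Rasgrp1 (-0.59 ± 0.001) and the pseudogene Ppp3r1-ps4 (-0.59 ± 0.09) passed as well, and Ppp1r2 (0.80 ± 0.25), Nudt3 (0.72 ± 0.35), Spock3 (0.62 ± 0.14) and Trank1 (0.59 ± 0.12) passed in the other direction. The rule asks only for the sign of the indirect ratio, which as labelled was smaller than the direct one in each. It was -0.43 for Btg2, -0.06 for Dusp6, -0.50 for Rasgrp1 and -0.30 for Ppp3r1-ps4. For Ppp1r2 it was 0.11, for Nudt3 0.25, for Spock3 0.04 and for Trank1 0.36. As labelled it sums 2 ratios, tumor-bearing versus food-restricted and food-restricted versus freely feeding. They offset each other for Dusp6 (-0.40 and 0.34), Ppp1r2 (0.44 and -0.33), Spock3 (0.36 and -0.32) and Nudt3 (0.44 and -0.19). They did so less for Btg2 and Ppp3r1-ps4, and for Rasgrp1 and Trank1 the second was near 0. With the food-restricted versus freely feeding pair turned, the offsetting ratios add up instead, and all these genes passed again. Fos measured -0.29 ± 0.11, Fkbp5 0.20 ± 0.14 (0.02 on a dimmer probe), Htr2a -0.24 ± 0.10, Npy 0.09 ± 0.03 and Ttr -0.25 ± 0.19. Dimmer probes gave -0.17, -0.02 and -0.02 for Htr2a and -0.01 for Ttr. The glucocorticoid-responsive list had a median of 0.02 over 25 genes (73.4th percentile), with orientations at 0.07 and -0.12. The inflammation and acute phase list had a median of 0.00 over 45 genes (52.8th percentile), the interferon and antigen presentation list 0.03 over 34 (89.1th percentile) and the microglia list 0.01 over 22 (61.7th percentile). In all, 12 transcripts passed the rule as labelled, 6 higher and 6 lower, out of 254 with a mean ratio of at least 1.5-fold and both orientations on the same side, and all conditions held for 254 with the food-restricted versus freely feeding pair turned. Both arrays of this pair were extracted on another day than the other 4, so day and comparison cannot be told apart. The count was 32 without array 1 and 66 without array 2 of the pair. Those counts lack the condition on both orientations and use the dye effect of the other pairs, so they are not counts under the same rule.

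**Figure D2:**
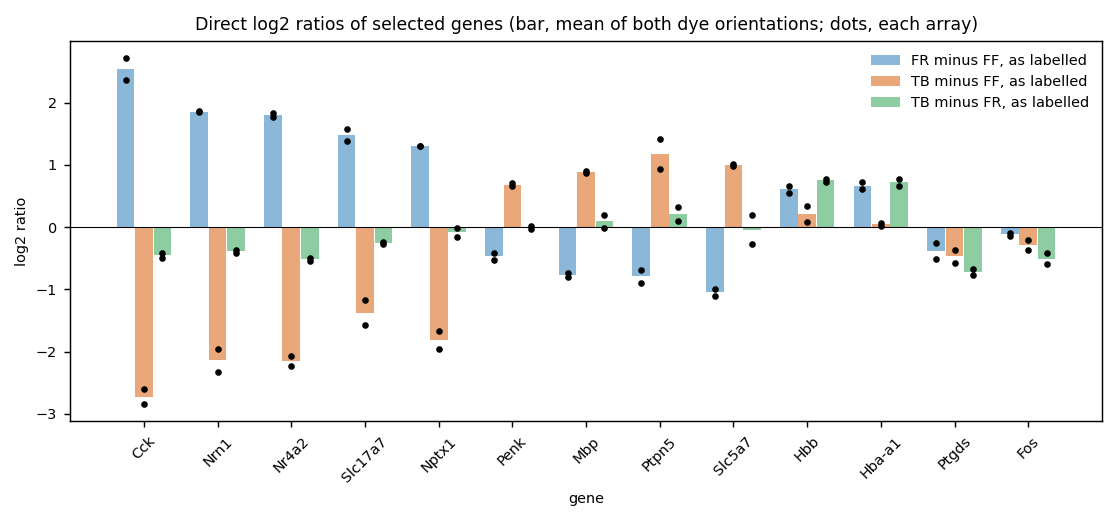
Bars give the direct log2 ratio (y axis) of selected genes (x axis) in the 3 comparisons, as labelled, as the mean of the 2 dye orientations, and dots give each array. For Cck the bars stand at 2.54, -2.73 and -0.45, and for Hbb at 0.61, 0.21 and 0.75.

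The tumor-bearing versus food-restricted pair sets rats of like body weight against each other, with and without a tumor. These pools were the closest, and the SD of their log2 ratios was 0.08 across transcripts, against 0.14 and 0.15 for the pairs with the freely feeding pool. Ptgds, the prostaglandin D synthase abundant in meninges and choroid plexus, was 1.65-fold lower in the tumor-bearing pool (-0.72 ± 0.07), though its indirect ratio as labelled was only -0.09. That ratio subtracts its food-restricted versus freely feeding value (-0.39) from its tumor-bearing versus freely feeding value (-0.47). With the food-restricted versus freely feeding pair turned the 2 add up instead, and Ptgds passed under both readings. The hemoglobin genes Hbb (0.75 ± 0.04), Hba-a1 (0.72 ± 0.07) and Hbb-b1 (0.71 ± 0.04) were higher. They did not carry that sign in the indirect ratio as labelled and did so with the food-restricted versus freely feeding pair turned.

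The medians of 3 gene lists were lower in the tumor-bearing pool on both arrays and below all matched random lists. The immediate-early list had a median of -0.08 over 35 genes, with 10 above 0. Fos measured -0.51 ± 0.13, and, chosen after their values were seen, Egr2 measured -0.54 ± 0.10, Btg2 -0.51 ± 0.002 and Egr4 -0.42 ± 0.13. The glucocorticoid-responsive list had a median of -0.10 over 25 genes, with 5 above 0, and Fkbp5 measured -0.21 ± 0.07 (-0.08 on a dimmer probe), while Sgk1 at -0.44 ± 0.12 and Sult1a1 at -0.57 ± 0.20 were chosen after their values were seen. The meninges and fibroblast list had a median of -0.12 over 17 genes, with 3 above 0, and its members Igf2 (-0.52 ± 0.05) and Ogn (-0.53 ± 0.20) were chosen after their values were seen. No member of these lists had a mean past 1.5-fold with both orientations on the same side. The dopamine list had a median of 0.05 over 25 genes (99.9th percentile), with Drd1 at 0.31 ± 0.04 and Drd2 at 0.18 ± 0.01. The list of GABA and glutamate receptors and transporters lay about as far out, at 0.04 over 43 genes (99.8th percentile), with orientations at 0.09 and 0.00. It had a median of 0.05 (98.9th percentile) in food-restricted versus freely feeding. Fasting metabolism genes had a median of -0.02 over 35 (2.455th percentile), with orientations at 0.01 and -0.03.

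The cortical list had a median of 0.01 (73.0th percentile) in this pair. The projection neuron list had a median of 0.05 over 25 genes (99.8th percentile), with 19 above 0 and orientations at 0.14 and 0.00. Penk (-0.01 ± 0.03), Tac1 (0.00 ± 0.29), Pdyn (-0.12 ± 0.24), Cartpt (0.01 ± 0.12), Npy (-0.02 ± 0.14), Ttr (0.01 ± 0.08), Htr2a (-0.05 ± 0.07) and Htr2c (0.00 ± 0.03) lay within the spread of the orientations. Dimmer probes gave -0.10 for Penk and 0.15 for Ttr. The inflammation list had a median of -0.01 (18.7th percentile) and the interferon list 0.01 (77.5th percentile). Chst1 (0.68 ± 0.05) and Bcat1 (0.61 ± 0.16) were higher and the channel gene Kcnj13 lower (-0.59 ± 0.06, well above background in 3 of 4 tumor-bearing channels), past all conditions with the food-restricted versus freely feeding pair turned. As labelled, 5 transcripts passed, which were Ptgds, LOC362664 (-0.65 and -0.64 on its arrays), Sytl1, AI170064 and BM986545, of which the 3 without a gene symbol were named after their values were seen. The last 3 rested on the array with the tumor-bearing pool in Cy5, at 2.85, 2.87 and 1.87, against 0.14, 0.11 and 0.15 on the other. With the food-restricted versus freely feeding pair turned 12 passed, 8 higher and 4 lower. Leaving out array 1 or 2 of this pair gave counts as labelled of 14 and 32, with no condition on both orientations. The count was 2 without array 2 of food-restricted versus freely feeding, and 2 without array 1 of tumor-bearing versus freely feeding.

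**Figure D3:**
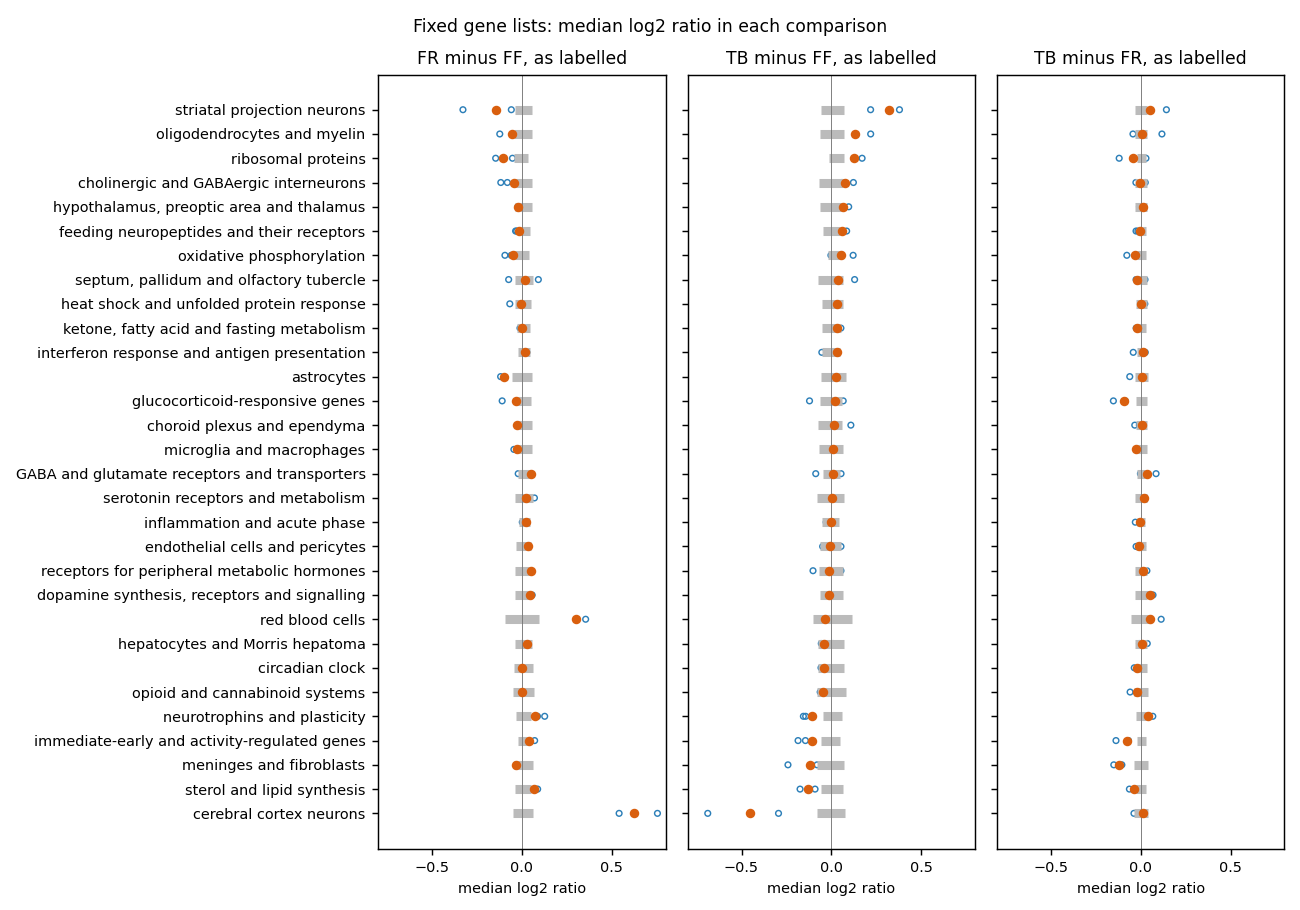
Orange dots give the median log2 ratio (x axis) of each of the 30 fixed gene lists (y axis) in the 3 comparisons as labelled, open circles the median on each of the 2 arrays, and grey bars the central 95% of 10000 matched random lists. The cerebral cortex list stands at 0.63, -0.45 and 0.01 and the projection neuron list at -0.14, 0.32 and 0.05.

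The 2 comparisons against the freely feeding pool share that pool, which by itself moves their ratios together. Across transcripts they correlated at r = -0.71 as labelled, with a covariance of -0.0153, where 3 exchangeable pools with the same array error gave 0.27 and 0.00447 in simulation. No transcript passed the rule in both as labelled, since 0 passed in food-restricted versus freely feeding. With that pair turned 35 were higher and 112 lower in both (0.163 and 0.664 for independent lists of those sizes), which follows from the choice of sign and tests nothing. With 1 freely feeding pool the control could not be split.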

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

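The tests on turned pairs, array error and immediate-early genes, and the comparison of cortical with oligodendrocyte genes, were chosen after the results were seen. In 13 of the 30 gene lists the medians of single arrays lay on opposite sides for the pools labelled food-restricted and tumor-bearing, each against the freely feeding pool, and this difference was not tested across animals. In 6 of them both medians were also outside the central 95% of matched random lists, and there the difference, tumor-bearing minus food-restricted, was -1.08 for cerebral cortex neurons, 0.46 for striatal projection neurons, 0.23 for ribosomal proteins, -0.20 for sterol and lipid synthesis, -0.18 for neurotrophins and plasticity, and 0.12 for cholinergic and GABAergic interneurons. In the other 7 it was -0.34 for red blood cells, -0.15 for immediate-early genes, 0.088 for hypothalamus, preoptic area and thalamus, 0.074 for feeding neuropeptides, -0.042 for the circadian clock, 0.029 for fasting metabolism and -0.026 for inflammation, though for the circadian clock and fasting metabolism the medians over both arrays lay on the same side. These differences rest on the labelled direction: with food-restricted versus freely feeding turned, 2 lists lay on opposite sides in place of 13, and the differences of the 13 ran from -0.067 to 0.26, with 0.17 for cerebral cortex neurons. Hybridised directly, the same pools differed by list medians from -0.079 to 0.053, and in 7 of the 13 the direct ratio had the other sign than the labelled difference.

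The ratios of the 3 pairs do not close around the loop, and array error alone is argued against: the sum of the ratios had 1.94 times the SD it gives (1.28 with median centring only, within the limit of 1.5), and direct and indirect food-restricted versus freely feeding ratios, from separate arrays, correlated at r = -0.80 (-0.78 with median centring only), which error does not give. Spatial trends are argued against too, as the sum had 2.69 times the SD expected after block medians were subtracted. Turning tumor-bearing versus freely feeding alone brought the SD to 1.11 times that expected, within that limit, which is lenient if the expected SD is too large. That turning is argued against by the direct and indirect tumor-bearing versus food-restricted ratios. They then correlated at r = -0.49 across transcripts, where matching directions give a value above 0. With the food-restricted versus freely feeding pair turned the SD was 0.67 times that expected, so exchanged labels of that pair, or equally of both pairs with the tumor-bearing pool, are a candidate explanation. Which of these applies stays open, and with it whether cortical transcripts were higher or lower in the freely feeding pool than in both others, although the titles, which name the Cy5 pool first on 4 arrays and the Cy3 pool first on the 2 of food-restricted versus freely feeding, set that pair apart.

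Cortical and striatal transcripts went opposite ways between the freely feeding pool and the others. A lower share of projection neurons met its planned test, as a second striatal list of 26 measured genes, 2 of its genes shared with other lists, lay opposite the cortical list (0.02th and 99.99th percentile), but alone it is argued against, since other cell types would then move alike and the cortical and oligodendrocyte lists lay 0.68 and 0.59 apart, beyond the spread of their array medians (0.18 and 0.31). A different share of cortical tissue in the dissected samples stays open: a second cortical list of 30 measured genes, 6 of its genes shared with other lists, lay on the side of the first in both comparisons, at the 97.9th percentile or beyond, but with medians of 0.14 and -0.06 against 0.63 and -0.45 for the first. Immediate-early activity cannot be told apart from it: the list without its 1 cortical gene lay on the same side at the 98.95th percentile or beyond. The full list lay only at the 94.2th percentile in food-restricted versus freely feeding, with 22 of 35 genes above 0. On the opposite side there were Fos (-0.12) and, chosen after their values were seen, Egr2 (-0.39), Egr4 (-0.19) and Nr4a1 (-0.15). The reduced list had medians of only 0.05 and -0.12 and still held Nr4a2 (1.79 and -2.16), which moved with the cortical genes. Between the tumor-bearing and food-restricted pools its median was -0.10, below all matched random lists, where the cortical list stood at 0.01. In that pair the immediate-early list thus moved without the cortical list. A response to feeding or to the tumor, which the design names, remains untested, since each group was 1 pool.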

How the results depend on the processing

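The turned pairs, block medians and symbol-only counts below were chosen after seeing the data. As labelled, food-restricted versus freely feeding gave 0 transcripts, tumor-bearing versus freely feeding 12 and tumor-bearing versus food-restricted 5, in that order below. The software's log ratio and the series matrix gave 2, 59 and 27, the last with 6 higher and 21 lower against 3 and 2, limma over the arrays at an adjusted p under 0.05 1329, 1423 and 15, and no sign conditions 211, 254 and 15. Offset 0 gave 27 and 11 for the latter comparisons, 1.3-fold 61 and 39, 2-fold 0 and 3, and the loop fit 4 and 57. Turning food-restricted versus freely feeding gave 211, 254 and 12, the loop fit with it turned 221, 233 and 11, and turning tumor-bearing versus freely feeding 198, 242 and 2. Tumor-bearing versus food-restricted gave 2 with both channels above background everywhere, 3 with block medians subtracted and 2 with symbols only, which tests fewer genes. Leaving out 1 array gave 0 to 3, 12 to 66 and 2 to 32 transcripts, by a looser rule where the array belonged to the pair counted. Of 30 lists, 12, 11 and 11 lay outside the central 95%, with 8 to 15, 7 to 11 and 7 to 11 when 1 array was left out, and 9 of the first 12 among the 15. The correlation of the comparisons against the freely feeding pool was -0.71, -0.71 to -0.40 without 1 array, and 0.16 in the loop fit, which forces unclosed ratios to close. In that fit the tumor-bearing versus food-restricted medians turned to 0.054 for ribosomal proteins, 0.018 for oxidative phosphorylation and -0.061 for neurotrophins, and the last to 0.0019 in tumor-bearing versus freely feeding. When 1 array was left out, feeding neuropeptides in tumor-bearing versus freely feeding ran from -0.021 to 0.058, and in tumor-bearing versus food-restricted oxidative phosphorylation ran from -0.051 to 0.011 and Sytl1 from -0.080 to 3.07. A reversed sign was counted only for gene ratios past the rule, as labelled or turned, and for list medians outside the central 95%. Within the 107 gene ratios and 90 list medians run, 1 and 5 reversed in that sense under any alternative. Changes of sign in the others were not counted. Apart from the causes named, the cause was not tested. The share of features well above background was lowest, 93.2%, in Cy5 of tumor-bearing versus freely feeding array 2, which limits what that pair shows for dim transcripts.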

Other observations

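Both tests on hemoglobin, and the spread each gene had to exceed, were chosen after its values were seen. Genes of sterol and lipid synthesis had a median of 0.07 over 26 genes in food-restricted versus freely feeding (99.8th percentile) and -0.13 in tumor-bearing versus freely feeding, as labelled. Among them, chosen after its values were seen, Hmgcs1, a synthase of the cholesterol pathway, measured 0.44 ± 0.03 and -0.58 ± 0.12. Neurotrophins and plasticity genes had medians of 0.07 and -0.11 over 32 genes, and among them, by the same later choice, the synaptic vesicle gene Syp measured 0.58 ± 0.26 and -0.55 ± 0.10. Ribosomal protein genes had medians of -0.11 and 0.12 over 68 genes, and oxidative phosphorylation genes -0.05 (1.37th percentile) and 0.05 over 54. The last value lay within the central 95% of random lists (89.6th percentile), with orientations at 0.12 and -0.002. Between the tumor-bearing and food-restricted pools these lists stood at -0.04 (0.51th percentile), 0.04 (99.6th percentile), -0.04 (0.03th percentile) and -0.03 (0.36th percentile), all outside the central 95%, and the ribosomal orientations were 0.03 and -0.12.

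In the loop as labelled, Hba-a1, Hbb and Hbb-b1 were higher in the food-restricted than in the freely feeding pool and lower than in the tumor-bearing pool, while they differed by 0.04 to 0.21 between the tumor-bearing and freely feeding pools. Hbe1 (0.05 ± 0.24) and Hbg1 (0.01 ± 0.12) did not stand apart with them in tumor-bearing versus food-restricted. With the food-restricted versus freely feeding pair turned, the first 3 genes were lower in the food-restricted pool than in both others, and with both tumor-bearing pairs turned they were higher. A different share of vessel cells is argued against, as the endothelial and pericyte list lay at the 16.4th percentile with a median of -0.01 and an SD of 0.10 between members, against a median of 0.71 over the hemoglobin genes. A different amount of blood may account for it and cannot be told apart from other sources, as the erythroid gene Alas2 lay on the same side but measured 0.069 ± 0.11, within its spread, and the second red blood cell list 0.02 over 20 genes, 7 of them in other lists.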
